A study of Mus musculus with 6 samples.

How the data were processed

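Liver RNA of 3 S1P lyase knockout mice and 3 WT mice was extracted with TRIzol and labelled with the standard Affymetrix protocol, per the labels' protocols. The genotype of each animal comes from the labels, which number the animals and give no batch, sex, litter or age. Replicates are separate mice and are numbered within a group only to name them.

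The deposited values are on the log2 scale, 1 value per probe set and array, as made by the authors. That they are log2 was settled from their range, since another base would exceed what a 16-bit scanner can record. Per the submitters' processing notes the tool was MAS5, named without a version or a role. Background correction, scaling and summarization are not given in the sources used here. Low values spread less between arrays than MAS5 signals on a log2 scale usually do, so another summarization is possible, and the method behind the values stays unknown. No detection calls were used, so a low value cannot be told from background. A summary with background left in understates the fold changes of dim genes.

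The table held 45101 probe sets, 64 of them array controls. A platform annotation gave 34958 probe sets exactly 1 gene symbol, 932 several and 9211 none listed. Of those with 1 symbol, 34754 were matched by gene identifier to an annotation of the mouse assembly GRCm38.p6, which was used for names and for the order of genes along a chromosome only. Control probe sets and probe sets whose mean over the 6 arrays lay under the 40th percentile (3.58 log2) were left out, leaving 27022 tested probe sets. Each gene was represented by its brightest tested probe set with exactly 1 symbol, giving 13370 genes. Of the changed genes, 1171 had more than 1 tested probe set. Another probe set was called the same way in 577 of these and the opposite way in 16, none of them among the genes chosen by the naming rule. Of the changed genes chosen by that rule with more than 1 tested probe set, Hamp2, Lipg, Top2a, Ddit3, Degs1, Clec4g, Kdsr and Gusb had no other probe set called.

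Genotypes were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, two-sided, on the deposited values without further normalization or covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and "rose" and "fell" are used of called genes. Folds are powers of 2 of the log2 difference, knockout minus WT. Single values per array were compared with an exact permutation test, whose smallest two-sided p with 3 against 3 is 0.1.

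In all, 36 lists of pathway genes and cell type markers were fixed before the data were examined, holding 675 genes, of which 560 were tested. The 33 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, two-sided, and again with an estimated correlation, with Benjamini-Hochberg adjustment over lists. Members' p-values were also adjusted over each list alone. No gene is held by more than 1 list, though the liver's own cells express many of the markers. Genes within 100 annotated genes on each side of Sgpl1 were compared with all others by Fisher's exact test.

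The genes named are Sgpl1, the 12 highest rises and 12 steepest falls among called genes whose knockout and WT values do not overlap (unnamed and predicted genes would be skipped, and 0 were), and up to 4 members of each list with the smallest adjusted p, or up to 8 in the sphingolipid and PPAR-gamma lists. Other genes named were chosen after their values were seen: Cyp7a1, Abcc4, Hamp, Tnf, Il1b, Cxcr2, Cd3e, Cd163, Timd4, C1qa, C1qb, C1qc, Fasn, Alb, Afp, Dnajc12 and Pbld2 in the results, and those of the closing part. Among the 159 genes the rule names, 16 have a probe set marked as shared with related transcripts, Cxcl1, Grn, Apoa4, Acot3, Mgll, Ghr, Dbp, Mup3, Ttr, Epcam and Xist besides those named with the top genes.

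The fit was tested on simulated data with the means and spread of the 13370 genes, 3 against 3 arrays and 200 changed genes in each of 20 simulations. It called 17.3% of genes changed by 0.5 log2, 92.7% of those changed by 1 and 99.4% of those changed by 2, and 6.32% of its calls fell on unchanged genes. In the data 2482 genes were called, far more than the 200 changed in a simulation. The Benjamini-Hochberg cutoff depends on how many genes change, so the shares called, above all at 0.5 log2, may differ in the data. A list of 20 genes shifted by 0.5 log2 was called in 20 of 20 simulations, and 0 unshifted lists were. The simulated genes varied independently of each other. The simulations therefore do not show how often camera calls unshifted lists of correlated genes, as real lists can be (estimated correlation 0.678 for interferon genes).

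Settings tried beside these were no filter, a filter at the 60th percentile, quantile normalization, median centring, no intensity trend, array quality weights, the mean of a gene's probe sets, camera with estimated correlation, and leaving out each array. Centring each array on hepatocyte markers or on the poly-A controls was added after seeing the data. Bootstrap intervals used 10000 resamples of genes or probe sets, so they do not measure the spread between arrays.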

Results

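RNA from the livers of 3 S1P lyase knockout mice and 3 wild-type (WT) mice was labelled with biotin and hybridised to 6 Affymetrix arrays, 1 per animal. S1P lyase, encoded by Sgpl1, is the enzyme that irreversibly breaks down sphingosine 1-phosphate (S1P), a signalling lipid and the last intermediate of sphingolipid breakdown. The animals had a mixed genetic background of the C57BL6 and 129sv strains. The comparison asks which liver transcripts differ when the enzyme is missing, with genes of lipid metabolism as a stated interest of the study. The number of arrays, 3 per group, limits the precision of every value.

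Liver profiles were closer to each other within a genotype than between genotypes. Across the tested genes, each read by its brightest probe set, the correlation between arrays was 0.983 to 0.99 within the knockout group. It was 0.979 to 0.983 within the WT group and 0.936 to 0.95 between groups. The array medians differed little, at 4.08 ± 0.01 log2 (SD, n = 3) in knockout and 4.11 ± 0.03 in WT (exact permutation test, two-sided, p = 0.3). Control probe sets did differ with genotype. The signal at the 3' end minus that at the 5' end, a measure of transcript integrity, was higher in knockout by 0.45 log2 for Actb, 0.47 for Gapdh and 1.01 for Pcx. For each of these 3 transcripts, all knockout arrays lay above all WT arrays (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 arrays allow). The bacterial poly-A control RNAs, which are added to a sample before labelling, were brighter in knockout by a mean of 0.75 log2, with all 24 probe sets higher in every knockout array than in every WT array.

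The scale of the arrays therefore matters for small differences. With each array centred on the poly-A controls, a setting chosen after seeing the data, every probe set difference is lower by 0.749 log2, 3' minus 5' values do not change, and 590 of the 1400 genes that rose on the deposited scale had risen by less than that.

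**Figure D1:**
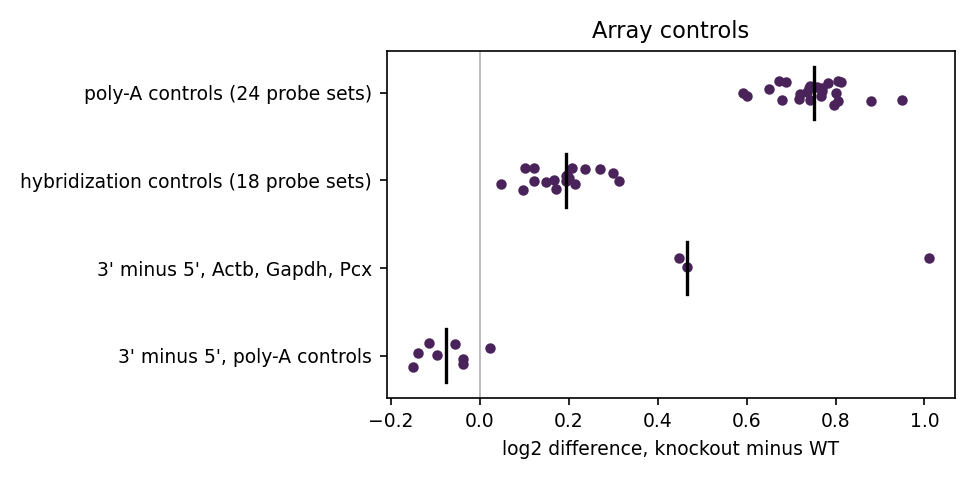
Difference between the knockout mean and the WT mean (log2, horizontal axis) for the array's control probe sets, with 1 point per probe set or per transcript and a bar at each median. The poly-A controls lie around 0.75, the hybridization controls around 0.19, the 3' minus 5' values of 3 liver transcripts at 0.45 to 1.01 and those of the poly-A controls near 0.

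Sgpl1, the targeted gene, was 15.7-fold lower in the knockout livers. Its brighter probe set read 2.78 ± 0.28 log2 (SD, n = 3) in knockout and 6.75 ± 0.13 in WT, a difference of -3.98 (SE 0.16, limma adjusted p = 1.5e-05). The other Sgpl1 probe set read 3.2 ± 0.18 against 6.25 ± 0.32. The knockout mean lay below the 3.58 log2 level under which probe sets were left out as dim, so this fold is limited by background. All 3 knockout arrays lay below all 3 WT arrays on both probe sets. Where the probes lie relative to the deleted part of the gene is not given in the sources used here.

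The knockout livers differed from WT in 2482 of 13370 genes tested (18.6%), of which 1400 rose and 1082 fell (limma, Benjamini-Hochberg adjusted p under 0.05). A change of at least 2-fold was seen in 525 genes that rose and 216 that fell, and one of at least 8-fold in 39 and 7. The highest rises were those of acute phase proteins, which the liver secretes in inflammation. Orm2 rose 133-fold (7.06 log2, SE 0.34), Lcn2 61.9-fold, Saa3 51.7-fold, Saa1 44.4-fold and Saa2 43.7-fold. Granulocyte genes came next: S100a8 rose 36-fold, S100a9 30.7-fold, Ngp 27.1-fold, Chil3 25.8-fold, Prtn3 23.0-fold and Camp 22.3-fold. Slfn4, a Schlafen family gene of myeloid cells, rose 24.1-fold.

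Besides Sgpl1, the steepest falls were those of Hamp2 and Thrsp. Hamp2, a gene of the hepcidin family, fell by 4.06 log2 (SE 0.77), and Thrsp, which promotes fatty acid synthesis, by 3.71 (SE 0.49). The other tested probe set of Hamp2 was not called, while 2 further probe sets of Thrsp fell as well. Of cytochrome P450 genes, Cyp4f14 was 10.8-fold lower in knockout, Cyp2c55 10.2-fold and Cyp2f2 7.03-fold. Car3, a carbonic anhydrase, was 10.1-fold lower, Keg1 9.88-fold, the glutathione transferase gene Gstm3 6.97-fold, the hydroxyacid oxidase gene Hao2 6.52-fold and the carboxylesterase gene Ces1f 6.47-fold. Clec4f, a lectin of resident liver macrophages (Kupffer cells), was 7.04-fold lower. Limma adjusted p-values of these top 12 rises and falls were 0.00993 or lower, and in each gene all knockout values lay apart from all WT values. The probe sets of Saa2, S100a8, Hamp2, Gstm3 and Ces1f are of a kind that can also read related transcripts.

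Values per animal were apart in 40.8% of the genes tested, where chance gives 10%. The count of changed genes depended on single arrays: it was 1339 without knockout replicate 2, 1428 without knockout replicate 1 and 1625 without WT replicate 1. It also depended on the scale, with 377 genes higher and 10120 lower in knockout when arrays were centred on the poly-A controls, and 2765 higher and 438 lower when they were centred on hepatocyte markers. Both of these centrings were chosen after seeing the data.

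**Figure D2:**
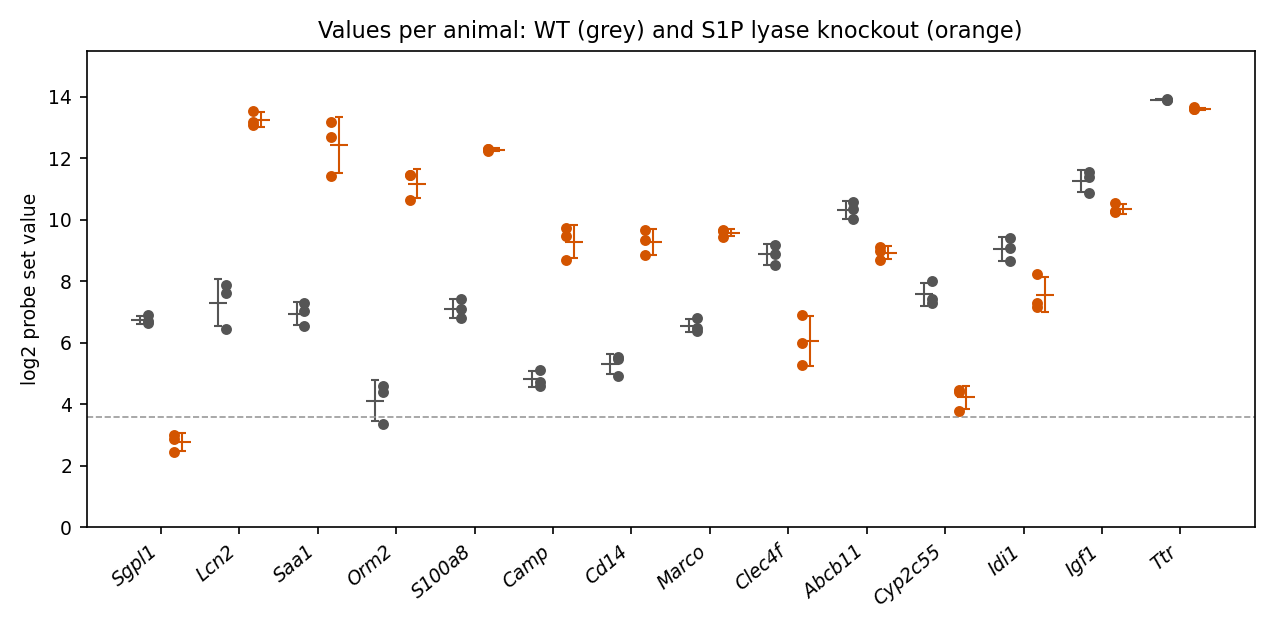
Log2 probe set value (vertical axis) of 14 genes in each WT (grey) and knockout (orange) liver, with the mean and SD of 3 animals beside the points. The dashed line marks the 3.58 log2 level under which dim probe sets were left out, and Sgpl1 lies below it in all knockout livers. Lcn2, Saa1, Orm2, S100a8, Camp, Cd14 and Marco are higher in every knockout liver, and Clec4f, Abcb11, Cyp2c55, Idi1, Igf1 and Ttr are lower, as deposited.

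Gene lists fixed before the data were examined were then compared with all other tested genes by limma's camera. With its preset correlation between genes, 18 of 33 lists tested differed, 11 upwards and 7 downwards. With a correlation estimated from the 6 arrays, 0 lists passed, the smallest adjusted p was 0.109, and 6 lists had an unadjusted p under 0.05. Higher correlation was not the whole reason for this loss. In the bile acid list the estimate was -0.0123, below the preset 0.01, yet camera's unadjusted p went from 2.02e-05 to 0.00911. Among the other lists that passed, the estimate lay above 0.01 in all but the male-biased liver genes (-0.154). The direction of a list that passed is therefore given with both p-values, and that of other lists with the preset one. It is a shift against the other genes tested.

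Most acute phase genes rose. Over all genes tested, 21 of 28 members rose and none fell, with a median difference of 1.5 log2, and 25 rose when adjusted over the list alone (camera adjusted p = 1.66e-17, adjusted p = 0.215 with an estimated correlation). Besides the top genes, Cd14, the co-receptor for bacterial lipopolysaccharide, rose 15.7-fold. Hamp, the gene of the iron hormone hepcidin, was lower by 1.46 log2 (SE 1.24) without passing the test. Of the inflammatory cytokine and NF-kappaB target genes, 13 of 21 rose and none fell, and 15 rose when adjusted over the list alone (median 0.97, adjusted p = 8.13e-09, adjusted p = 0.109 with an estimated correlation). Tlr2 rose by 2.27 log2 (SE 0.18), Vcam1, an adhesion molecule for leukocytes, by 1.95 (SE 0.16), and the chemokines Cxcl1 and Ccl6 by 2.95 (SE 0.32) and 1.65 (SE 0.13). Tnf and Il1b differed by 0.03 and 0.44 log2 and did not pass. Interferon response genes rose in 7 of 19 cases and fell in none, 11 rising when adjusted over the list alone (median 1.25, adjusted p = 1.04e-05, adjusted p = 0.489 with an estimated correlation). The interferon list's median was 0.77 with array quality weights and 0.83 without WT replicate 3. Rsad2, Oas1a, Usp18 and Ifit2 rose by 1.56 to 1.7 log2. Ifit2 no longer passed without knockout replicate 1 or 2 or WT replicate 1. These rises came in arrays whose 3' to 5' values were also higher, by 0.45 log2 for Actb, as were their neutrophil transcripts (list median 3.98).

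**Figure D3:**
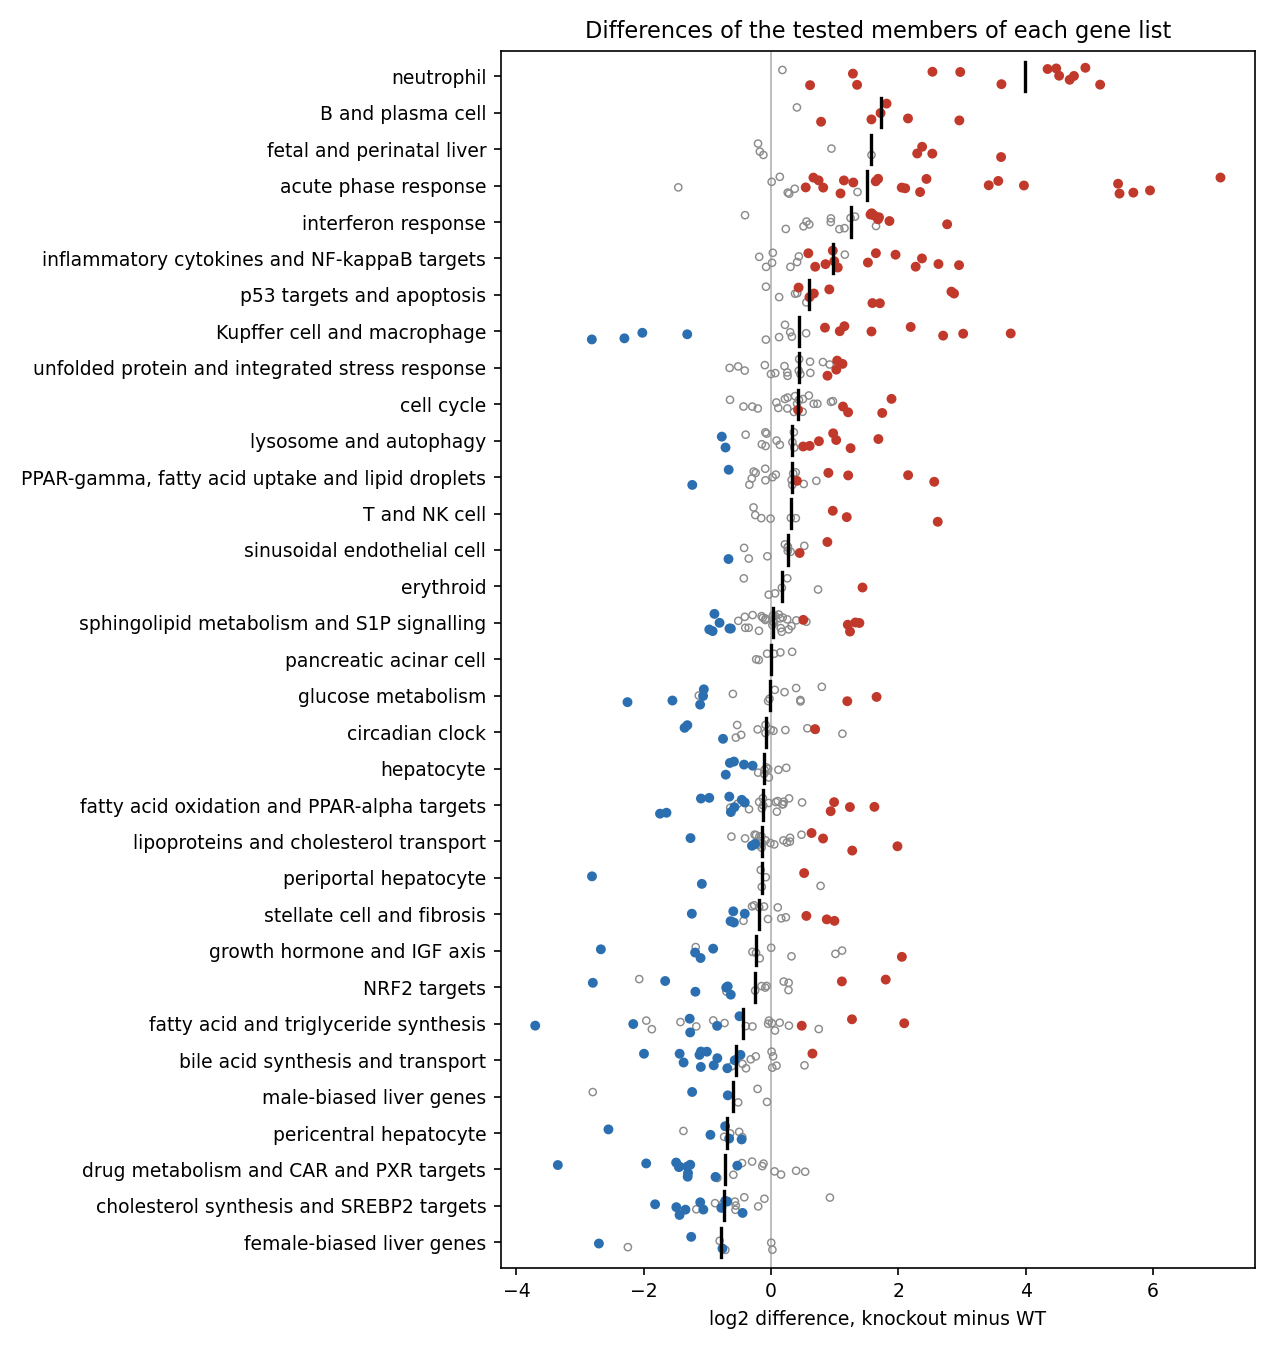
Log2 difference, knockout minus WT (horizontal axis), of each tested member of 33 gene lists, ordered by the list's median, which is drawn as a bar. Filled red and blue points passed the test upwards and downwards as deposited, and open points did not pass. The neutrophil list has the highest median (3.98), and the female-biased liver genes the lowest (-0.79), and centring on the poly-A controls lowers every point by 0.749.

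Neutrophil and B cell transcripts were higher in the knockout livers. Neutrophil genes rose in 13 of 14 cases and fell in none, over all genes and also when adjusted over the list alone (median 3.98, camera adjusted p = 8.77e-18, adjusted p = 0.109 with an estimated correlation). They include genes of the primary granules, which form early in granulocyte development, such as Prtn3, and of the secondary granules, such as Camp and Ngp. The chemokine receptor gene Cxcr2 was the member that did not pass, at 0.18 log2 (SE 0.14). B and plasma cell genes rose in 6 of 7 cases under both adjustments (median 1.72, adjusted p = 6.6e-07, adjusted p = 0.155 with an estimated correlation). Pou2af1 rose by 2.96 log2 (SE 0.25), from a WT mean below the level for dim probe sets, and Cd79b, Cd79a and Ms4a1 by 2.15, 1.81 and 1.58. The T and NK cell list did not pass: 3 of 9 members rose and none fell under both adjustments (median 0.31, adjusted p = 0.106). On the poly-A scale its median is -0.44, above the -0.80 of all genes, and the list passed upwards against them (camera adjusted p = 0.0176). It passed without a filter on dim probe sets (adjusted p = 0.0443) and, with a median of 0.27, without WT replicate 2 (adjusted p = 0.0203), while the median was 0.17 with array quality weights (adjusted p = 0.191) and 0.20 without WT replicate 3 (adjusted p = 0.212). Its risen members were Gzma (2.62, SE 0.22), Il7r (1.19, SE 0.25) and Nkg7 (0.97, SE 0.14), while the T cell receptor gene Cd3e was at -0.28 (SE 0.12). Il7r no longer passed without knockout replicate 2 or WT replicate 1. In the erythroid list, 1 of 7 members rose under both adjustments, Slc4a1 by 1.43 log2 (median 0.17, adjusted p = 0.216, and median 0.02 without knockout replicate 2). The knockout arrays were those with the higher 3' to 5' values, by 0.45 log2 for Actb and 1.01 for Pcx.

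Macrophage genes moved both ways. In the list of Kupffer cell and macrophage genes, 8 of 18 rose, 4 fell and 6 did not pass, with 10 rising and 4 falling when adjusted over the list alone (median 0.44, camera adjusted p = 0.00864, adjusted p = 0.489 with an estimated correlation). The list's median is below 0 on the poly-A scale, and its call was lost with arrays centred on hepatocyte markers (adjusted p = 0.125). Without WT replicate 3 the median was 0.26 (adjusted p = 0.0493). Those that rose include Gpnmb, a glycoprotein of lipid-laden macrophages (3.76 log2, SE 0.36), the scavenger receptor Marco (3.02, SE 0.14) and Lyz2, the lysozyme of macrophages and granulocytes (2.70, SE 0.18). Those that fell were Clec4f (-2.82, SE 0.37), the complement receptor Vsig4 (-2.30, SE 0.23), the haemoglobin scavenger receptor Cd163 (-2.02, SE 0.36) and Timd4 (-1.32, SE 0.24), of which Clec4f, Vsig4 and Timd4 are typical of resident Kupffer cells. C1qa, C1qb and C1qc, the complement genes that most tissue macrophages express, differed by -0.08, 0.13 and 0.22 log2 (SE 0.18, 0.22 and 0.17) and did not pass. Cd163, Timd4 and the C1q genes were named after their values were seen. The same arrays had the higher neutrophil transcripts (median 3.98) and 3' to 5' values, by 0.45 log2 for Actb and 1.01 for Pcx.

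**Figure D4:**
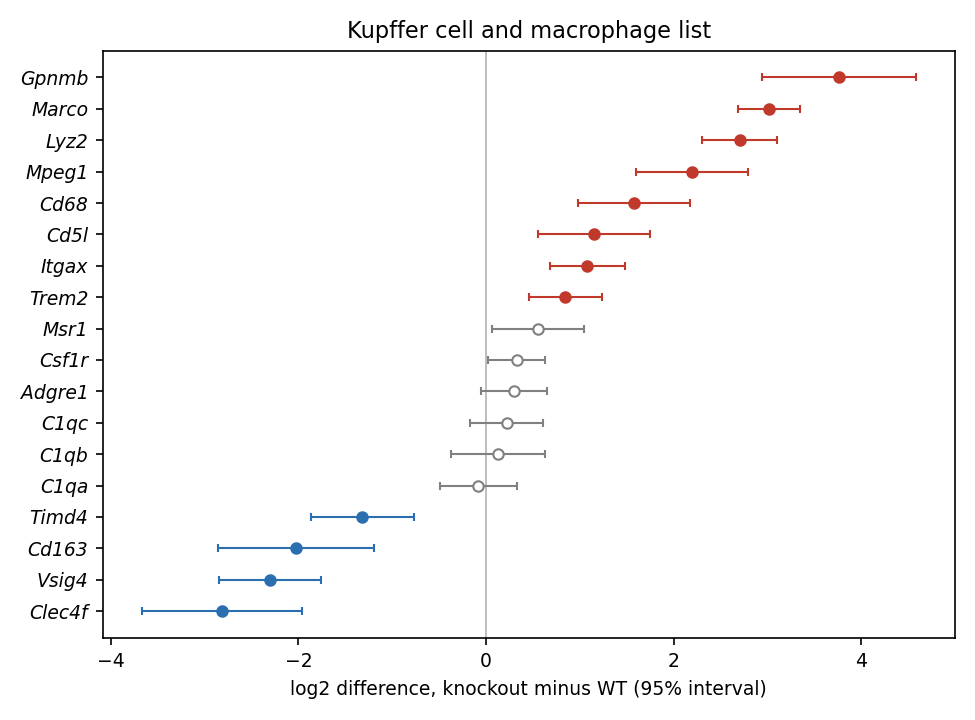
Log2 difference, knockout minus WT, of each of 18 Kupffer cell and macrophage genes, with the 95% confidence interval of the limma fit as error bars. Clec4f, Vsig4, Cd163 and Timd4 lie below 0, and Gpnmb, Marco and Lyz2 have the highest values, on the deposited scale and on that of the poly-A controls.

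Sphingolipid genes moved both ways, and their list did not pass. Of 36 tested members, 5 rose, 6 fell and 25 did not pass, or 7 rose and 8 fell when adjusted over the list alone (median 0.03, camera adjusted p = 0.964). This list and those for lipid synthesis and PPAR-gamma were drawn up with a general recollection of the study, so they are not independent evidence. Cerk, which phosphorylates ceramide, rose by 1.39 log2 (SE 0.16), the ceramidase gene Acer2 by 1.32 (SE 0.30) and Psap, whose product activates sphingolipid hydrolases, by 1.20 (SE 0.14). Psap lies near Sgpl1 on chromosome 10, so a strain difference around the targeted gene cannot be told apart from a response. The ceramide synthase gene Cers2 fell by 0.81 (SE 0.11), the S1P receptor gene S1pr1 by 0.89 (SE 0.16), and Aldh3a2, which oxidises the aldehyde that S1P lyase releases, by 0.92 (SE 0.20). Degs1, which makes ceramide from dihydroceramide, was 0.51 higher (SE 0.12) as deposited and lower, at -0.24, on the poly-A scale. Acer2 lost its call without knockout replicate 1 or 2, and Aldh3a2 without knockout replicate 2 or WT replicate 1. Degs1 lost it without knockout replicate 2 or 3 or WT replicate 2 or 3.

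In the cholesterol synthesis list, 10 of 20 tested genes fell, none rose and 10 did not pass, and 15 fell and 1 rose when adjusted over the list alone (median -0.74, camera adjusted p = 1.04e-05, adjusted p = 0.215 with an estimated correlation). Idi1 fell by 1.49 log2 (SE 0.30), Tm7sf2 by 1.11 (SE 0.21), Ebp by 1.06 (SE 0.16) and the cholesterol transfer gene Stard4 by 0.72 (SE 0.13). Fatty acid and triglyceride synthesis genes fell in 6 and rose in 3 of 24 cases, or 9 and 4 when adjusted over the list alone, and the list did not pass (median -0.45, adjusted p = 0.14), though it did without WT replicate 1 (adjusted p = 0.0121) and with either of the centrings chosen after seeing the data (adjusted p = 0.00393 with hepatocyte markers and 3.43e-06 with poly-A controls). The fatty acid synthesis median was -0.14 without WT replicate 2 (adjusted p = 0.258), -0.71 with array quality weights (adjusted p = 0.0677) and -0.23 with arrays centred on hepatocyte markers. Idi1 no longer passed without knockout replicate 1 or 2. Besides Thrsp, Acss2 fell by 1.27 log2 (SE 0.22) and Dgat2, which makes triglyceride, by 0.85 (SE 0.14), while the desaturase gene Scd2 rose by 2.09 (SE 0.13). Fasn, the fatty acid synthase, was lower by 1.96 (SE 0.70) and did not pass, with a WT SD of 1.65. The same knockout arrays had higher neutrophil transcripts, with a median of 3.98, and higher 3' to 5' values, by 0.47 log2 for Gapdh.

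Fatty acid oxidation genes, many of them targets of PPAR-alpha, did not pass as a list. Of 29 members, 9 fell and 4 rose, or 11 and 4 when adjusted over the list alone (median -0.13, adjusted p = 0.14). The list passed without knockout replicate 1 (median -0.22, adjusted p = 0.0281) and without WT replicate 2 (median -0.16, adjusted p = 0.0384), while its median was -0.02 without knockout replicate 3 (adjusted p = 0.571) and -0.04 with array quality weights (adjusted p = 0.412). With arrays centred on hepatocyte markers it passed downwards against other genes (adjusted p = 0.0295) with a median of 0.09. Ehhadh, an enzyme of peroxisomal oxidation, fell by 1.75 log2 (SE 0.17). Acot3 fell by 1.64 (SE 0.26), the fatty acid binding protein Fabp1 by 0.97 (SE 0.12) and Etfdh by 0.63 (SE 0.11). In the list for PPAR-gamma, fatty acid uptake and lipid droplets, 5 of 22 rose and 2 fell, or 7 and 2 when adjusted over the list alone (median 0.33, adjusted p = 0.126). This list passed without a filter (adjusted p = 0.038), with the filter at the 60th percentile (adjusted p = 0.045) and without WT replicate 3 (adjusted p = 0.0408), and had a median of 0.21 without knockout replicate 1 (adjusted p = 0.19) or WT replicate 1 (adjusted p = 0.139). Pparg itself rose 1.87-fold (0.90 log2, SE 0.13), the fatty acid transporter Cd36 2.32-fold, and Fabp4 and Fabp5, which adipocytes and macrophages express, 5.91-fold and 4.45-fold. Mgll, a monoglyceride lipase, fell by 1.24 log2 (SE 0.16) and Cidea by 0.67 (SE 0.12), into the range of dim probe sets. Plin3 was 0.41 higher (SE 0.12) and is lower, at -0.34, on the poly-A scale, as is the list's median, at -0.42. Against the other genes the list passed upwards on that scale (camera adjusted p = 0.026), where the median of all genes was -0.80. Plin3 no longer passed when any single array was left out, and Fabp5 when any 1 of the 3 knockout replicates was. Lipoprotein and cholesterol transport genes rose in 4 and fell in 3 of 25 cases, or 4 and 4 when adjusted over the list alone, with a median of -0.14, a mean of 0.07 and a downward test (adjusted p = 0.964). Apoa4 and the sterol exporter Abcg1 rose by 1.99 and 1.27 log2 (SE 0.37 and 0.15), and Lipg fell by 1.27 (SE 0.16).

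Many bile acid and drug metabolism genes fell. Of 24 genes of bile acid synthesis and transport, 12 fell and 1, Abcc4, rose, with 12 and 2 when adjusted over the list alone (median -0.55, camera adjusted p = 6.67e-05, adjusted p = 0.109 with an estimated correlation). The bile acid median was -0.33 with arrays centred on hepatocyte markers. The bile salt export pump Abcb11 was 2.59-fold lower in knockout, the bile acid uptake carrier Slc10a1 2.15-fold, and the synthesis enzymes Akr1d1 and Hsd3b7 2.18-fold and 2.15-fold. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -2.0 log2 (SE 0.27) and fell. Abcc4 and Cyp7a1 were named after their values were seen. Drug metabolism genes and targets of the receptors CAR and PXR fell in 11 of 22 cases and rose in none, or 13 and 1 when adjusted over the list alone (median -0.72, adjusted p = 2.18e-05, adjusted p = 0.155 with an estimated correlation). CAR itself, encoded by Nr1i3, was 2.41-fold lower, and the glucuronosyltransferase genes Ugt2b1 and Ugt2b5 3.90-fold and 2.71-fold. NRF2 targets fell in 6 and rose in 2 of 17 cases, or 7 and 2 when adjusted over the list alone, and the list did not pass (median -0.25, adjusted p = 0.124). It passed with the filter at the 60th percentile (median -0.63, adjusted p = 0.0149), without WT replicate 2 (adjusted p = 0.0384), without knockout replicate 3 (adjusted p = 0.0431) and with either of the centrings chosen after seeing the data (median -0.03, adjusted p = 0.0125 with hepatocyte markers, and adjusted p = 0.00149 with poly-A controls). Hmox1, which degrades haem, rose by 1.80 log2 (SE 0.23), and Ephx1, a detoxifying hydrolase, fell by 1.19 (SE 0.18). The knockout arrays behind these falls are those with the higher 3' to 5' values, by 0.45 log2 for Actb and 1.01 for Pcx, and with the higher neutrophil transcripts.

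General hepatocyte markers differed little. In that list 5 of 13 fell and none rose, with 5 and 1 when adjusted over the list alone, and the median was -0.11 (camera adjusted p = 0.0473, adjusted p = 0.357 with an estimated correlation). The call was lost without WT replicate 1 (adjusted p = 0.139), WT replicate 3 (0.0738), knockout replicate 2 (0.056) or knockout replicate 3 (0.068), and under most other settings. The median was -0.20 without WT replicate 2 and with the mean of a gene's probe sets, and 0.11 with arrays centred on hepatocyte markers. Otc, of the urea cycle, fell by 0.65 log2 (SE 0.12), Serpinc1 by 0.43 (SE 0.08) and Ttr by 0.29 (SE 0.07, a call lost without any 1 array except knockout replicate 3), and Alb was at -0.05 (SE 0.07), named after its value was seen. Pericentral hepatocyte genes fell in 5 of 10 cases and rose in none, 9 falling when adjusted over the list alone (median -0.69, adjusted p = 6.6e-05, adjusted p = 0.357 with an estimated correlation), with Cyp1a2 5.88-fold lower. The same arrays had the higher neutrophil transcripts (median 3.98) and 3' to 5' values (1.01 for Pcx). In the periportal list, 2 of 7 fell and 1 rose under both adjustments (median -0.15, adjusted p = 0.593, and 0.0374 on the poly-A scale). With 1 array left out, that median ran from -0.26 to 0.05. The periportal genes Cyp2f2 and Hal fell by 2.81 and 1.09 log2, and Hsd17b13 was 0.52 higher as deposited and is lower, at -0.23, on the poly-A scale. Hal lost its call without knockout replicate 2 or WT replicate 1 or 2, and Hsd17b13 without knockout replicate 1 or 2 or WT replicate 1 or 2.

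Genes of endocrine and metabolic control moved in part. In the growth hormone and IGF list, 4 of 13 fell and 1 rose under both adjustments, and the list did not pass (median -0.24, adjusted p = 0.236). It did with the mean of a gene's probe sets (median -0.45, adjusted p = 0.0486) and with arrays centred on hepatocyte markers (median -0.02, adjusted p = 0.0341). The growth hormone median was -0.14 without WT replicate 2 (adjusted p = 0.386) and -0.40 without WT replicate 3 (adjusted p = 0.109). Igfals, which stabilises circulating IGF1, was 6.38-fold lower, Ghr, the growth hormone receptor, 2.16-fold and Igf1 1.88-fold, while Igfbp1 rose 4.15-fold. Igf1 lost its call without knockout replicate 1, Ghr without WT replicate 1, and Igfbp1 without knockout replicate 1 or 2 or WT replicate 2 or 3. Male-biased liver genes fell in 2 of 6 cases and rose in none, 4 falling when adjusted over the list alone (median -0.60, adjusted p = 0.0287, adjusted p = 0.215 with an estimated correlation). Female-biased ones fell in 3 of 8 cases and rose in none under both adjustments (median -0.79, adjusted p = 0.0413, adjusted p = 0.489 with an estimated correlation). Both sex-biased calls were lost without knockout replicate 3 (adjusted p = 0.0617 for each), and the female-biased one also without knockout replicate 2 (adjusted p = 0.0561) or WT replicate 1 (adjusted p = 0.148), with median centring (adjusted p = 0.0615) or with array quality weights (adjusted p = 0.0677). The female-biased median ran from -1.42 without knockout replicate 1 to -0.43 without knockout replicate 3. The male-biased median was -0.39 without a filter and -0.38 with arrays centred on hepatocyte markers. These arrays also had the higher neutrophil transcripts (median 3.98) and 3' to 5' values (1.01 for Pcx). Xist, which is transcribed from the inactive X chromosome, read 10.72 to 11.41 log2 in all 6 animals on the probe set tested, 10.45 to 11.10 on another and 6.46 to 7.62 on the remaining one, and the Y-linked genes Kdm5d, Eif2s3y and Uty read 1.77 to 3.08 over all their probe sets. These Y-linked values lie below the 3.58 log2 level for dim probe sets. By these transcripts all 6 animals read as female, which argues against a difference in sex between the groups. Xist was the 1 tested member of the sex-chromosome list, 0.46 higher in knockout (SE 0.12, adjusted p = 0.0321, and also past the threshold adjusted over the list alone), and it is lower, at -0.29, on the poly-A scale. It no longer passed without knockout replicate 1 or 2 or WT replicate 2 or 3. Glucose metabolism genes fell in 5 and rose in 2 of 17 cases, or 5 and 3 when adjusted over the list alone (median -0.02, adjusted p = 0.434), and the median ran from -0.11 to 0.16 with 1 array left out. The pyruvate kinase gene Pklr fell by 2.26 log2 (SE 0.42), Irs1, an adaptor of the insulin receptor, by 1.55 (SE 0.14), and the glucose transporter Slc2a2 by 1.11 (SE 0.17). Of 16 circadian clock genes, 3 fell and 1 rose, or 3 and 4 when adjusted over the list alone (median -0.09, adjusted p = 0.814), and the median ran from -0.15 to 0.09 with 1 array left out. Nr1d1 fell by 1.32 log2 (SE 0.24) and Nr1d2 by 0.76 (SE 0.15), while Nfil3 was 0.69 higher (SE 0.20) and is at -0.06 on the poly-A scale. Nfil3 passed when WT replicate 1 was left out but not when any other single array was.

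Some stress, cell cycle and fetal liver genes rose, while most members of those 3 lists did not pass. Targets of p53 rose in 8 of 13 cases and fell in none, 10 rising when adjusted over the list alone (median 0.60, camera adjusted p = 1.81e-06, adjusted p = 0.109 with an estimated correlation). Cdkn1a, an inhibitor of the cell cycle, rose 7.33-fold, Btg2 7.13-fold and Trp53inp1 3.02-fold. Cell cycle genes rose in 5 of 25 cases and fell in none, 7 rising when adjusted over the list alone (median 0.42, adjusted p = 0.000491, adjusted p = 0.499 with an estimated correlation). The proliferation marker Mki67 rose 3.71-fold and Top2a 3.35-fold, and Plk1 was 0.42 log2 higher (SE 0.11) and is lower, at -0.33, on the poly-A scale. Plk1 kept its call when WT replicate 3 was left out but not when any other single array was. Genes of the unfolded protein and integrated stress response rose in 4 of 20 cases and fell in none under both adjustments (median 0.44, adjusted p = 0.0213, adjusted p = 0.489 with an estimated correlation). These were Ddit3, Asns, Atf3 and Ppp1r15a, at 0.89 to 1.12 log2, genes of the integrated stress response, and the call of the list was lost without knockout replicate 3 (adjusted p = 0.195) or WT replicate 1 (median 0.26, adjusted p = 0.0594), with the filter at the 60th percentile (adjusted p = 0.0504) and with arrays centred on hepatocyte markers (adjusted p = 0.125). Ddit3 lost its call without knockout replicate 1 or WT replicate 1 or 2. Fetal and perinatal liver genes rose in 4 of 9 cases and fell in none under both adjustments (median 1.58, adjusted p = 0.00509, adjusted p = 0.315 with an estimated correlation). Igdcc4 rose 12.2-fold, Gpc3 5.79-fold, Cd24a 5.18-fold and Tff3 4.91-fold, and Afp, at 1.58 log2 (SE 0.70), did not pass. Tff3 lost its call without knockout replicate 1, and the list's median was then 0.67, and 0.95 with all arrays and no filter. Lysosome and autophagy genes rose in 7 and fell in 2 of 19 cases, or 9 and 2 when adjusted over the list alone (median 0.34, adjusted p = 0.0187, adjusted p = 0.215 with an estimated correlation). Ctss, a cathepsin of antigen-presenting cells, rose by 1.69 log2 (SE 0.23) and Grn by 1.25 (SE 0.10). With the mean of a gene's probe sets, the p53 median was 0.37 and the lysosome median 0.11. Centred on hepatocyte markers, the cell cycle median was 0.64, that of the stress response 0.66 and that of the lysosome list 0.56. The medians of the p53, cell cycle, stress response and lysosome lists lie below 0 on the poly-A scale, where the lysosome list no longer passes (adjusted p = 0.076). The same arrays had the higher neutrophil transcripts (median 3.98) and 3' to 5' values.

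The lists of other liver cell types did not pass. Sinusoidal endothelial genes rose in 2 and fell in 1 of 12 cases under both adjustments (median 0.26, camera adjusted p = 0.216, and median 0.16 without knockout replicate 2). Stab1 was 0.88 log2 higher (SE 0.14) and Clec4g fell by 0.67 (SE 0.19), and Stab2, 0.45 higher (SE 0.11), is lower, at -0.30, on the poly-A scale. Stab2 and Clec4g lost their calls without knockout replicate 1 or 2 or WT replicate 1 or 2, and Lrat of the stellate cell list without knockout replicate 1 or 2 or WT replicate 2. Stellate cell and fibrosis genes fell in 5 and rose in 3 of 17 cases under both adjustments (median -0.19, adjusted p = 0.339). Col4a1 and Timp1 rose by 0.99 and 0.87 log2, and Lrat, which stores vitamin A in stellate cells, fell by 1.24 (SE 0.28). None of the 6 tested pancreatic acinar genes passed under either adjustment, with a median of -0.01, a mean of 0.01 and a downward test (adjusted p = 0.964). Lists with under 5 tested members were not given to camera: none of 4 cholangiocyte genes and none of 2 white adipocyte genes passed, apart from 1 cholangiocyte gene, Sctr, that fell when adjusted over the list alone, and the medians were -0.11 and -0.17.

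Genes next to Sgpl1 on chromosome 10 did not change detectably more often than others. Among tested genes within 100 annotated genes on each side, 14 of 69 (20.3%) changed, against 2467 of 13300 elsewhere (18.5%), an odds ratio of 1.12 (95% confidence interval 0.573 to 2.04, Fisher's exact test, two-sided, p = 0.756). On the poly-A scale the odds ratio is 0.906 (Fisher's exact test, p = 0.769). Of the neighbours that changed, 11 rose and 3 fell, with Dnajc12 highest at 2.25 log2 (SE 0.24) and Pbld2 lowest at -1.49 (SE 0.12), both named after their values were seen. Psap, of the sphingolipid list, was among the neighbours that rose (1.20 log2, SE 0.14). Whether a strain difference around Sgpl1 moved single neighbours was not tested.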

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

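The tests of explanations in this part were chosen after the results were seen, except that of dimmer hepatocyte markers and that of further monocyte genes, whose outcome was predicted first. The 3' to 5' values of Actb and Gapdh were planned as a check, and the other control values were looked at later.

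Control probe sets, which enter no gene comparison, differed with genotype. The poly-A control probe sets were higher in the knockout arrays by a median of 0.751 log2. The 3' minus 5' difference was higher by 0.447 log2 for Actb, 0.465 for Gapdh and 1.01 for Pcx. The control probe set for the B1 repeat, a short repeated element found in many mouse transcripts, was higher by 0.749, at 9.14 ± 0.30 in knockout and 8.39 ± 0.13 in WT (SD, n = 3).

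Stronger hybridization or scanning of the knockout arrays was argued against as the whole cause. The poly-A controls rose by 0.556 log2 more than the hybridization controls (95% bootstrap interval 0.525 to 0.619). That interval is over probe sets, not arrays, and the poly-A array means had an SD of 0.278 log2 in knockout. All 24 poly-A probe sets were higher in every knockout array than in every WT array, against 8 of 18 hybridization probe sets. A less complete labelling reaction was argued against as well, since the poly-A controls' own 3' minus 5' value differed by -0.0752 while that of the liver transcripts rose. A higher ratio of control RNA to liver mRNA in the knockout samples is consistent with the values: the smallest median rise among the 4 control genes was 0.707, and the highest among hybridization controls 0.233. Whether that ratio came from less mRNA per amount of liver RNA, from partly degraded liver RNA that was labelled less well, or from more control added stays open. No biological explanation was tested, and genotype and the handling of the samples cannot be separated in this design.

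Bile acid, drug metabolism and cholesterol synthesis genes had a joint median of -0.652 log2. A lower share of hepatocyte RNA was not decided as a cause. The hepatocyte list lay 0.542 above these genes (95% bootstrap interval 0.143 to 0.771), but their lists were picked because they were lower. Bright hepatocyte markers may be near saturation and hide a fall: the 3 markers with a mean under 11 lay 0.58 above these genes (-0.0928 to 0.927), too few to decide. A loss of RNA quality that acts alike on genes of like signal was not decided: this median lay at percentile 0 of 10000 random lists matched on signal, but the lists were picked because they were lower. A lower share of hepatocyte RNA, loss of RNA quality of any kind and an effect of genotype on these pathways stay open.

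Granulocyte and monocyte genes rose while Clec4f, Vsig4, Cd163 and Timd4 fell. More residual blood of WT composition was argued against, as the neutrophil list lay 3.81 log2 above the erythroid list (95% bootstrap interval 1.35 to 4.55), though blood with more granulocytes stays open. Dilution of Kupffer cell RNA by other cells was argued against as the whole cause of these 4 falls: the genes, named because they fell, differed from the hepatocyte list by -2.05 (interval -2.71 to -1.21), and the upper 95% limit of each one's own difference was -0.76 or lower, while further Kupffer cell genes (median -0.149) lay close to that list. Entry of monocytes is consistent with the further monocyte genes, whose median was 2.01 (interval 1.01 to 2.3), but granulocytes and other leukocytes express several of them too. As a hypothesis, monocyte-derived cells and a changed state of Kupffer cells may both contribute, and bulk RNA cannot place these transcripts in cells.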

How the results depend on the processing

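The centrings on hepatocyte markers and on poly-A controls were chosen after the data were seen, and the other settings before. Under 7 planned settings of filter, scale, trend, weights and probe set, the count of changed genes ran from 2297 to 3158, against 2482, and no gene was called the opposite way. The share of higher calls was 56.4% as deposited, 86.3% with hepatocyte markers (2765 up, 438 down, median of all genes 0.17) and 3.59% with poly-A controls (median -0.80). The latter gave 10497 genes (377 up, 10120 down) and 21028 probe sets (619 up, 20409 down), against 4835 (2722 up, 2113 down). It subtracts the same amount from every gene of an array, with an SD of 0.278 log2 between knockout arrays, so these calls share 1 error. It reversed Degs1 (-0.24), Plin3 (-0.34), Plk1 (-0.33), Nfil3 (-0.059), Hsd17b13 (-0.23), Stab2 (-0.30), Cel (-0.60) and Xist (-0.29) by its construction. It also reversed the odds ratio near Sgpl1 (0.906), of which the cause was not tested. Of 158 named genes other than Sgpl1, 120 kept direction and call there and 143 with hepatocyte markers. Camera with estimated correlation called 0 lists instead of 18. With all 6 arrays kept, 16 to 22 lists passed under the other settings. Leaving out each array in turn gave 1339 to 2381 genes, 2517 to 4639 probe sets, 15 to 21 lists, odds ratios of 1.07 to 1.53 and Sgpl1 differences of -4.08 to -3.82. The lowest gene counts were without knockout replicate 2 (1339 genes, 2517 probe sets), knockout replicate 1 (1428, 2605) and WT replicate 1 (1625 genes). Fewer samples in the fit lower such counts by themselves. The hepatocyte, female-biased and stress response lists lost their call most often, and the cause was not tested. Lists for fatty acid synthesis, fatty acid oxidation, PPAR-gamma, NRF2, growth hormone, T and NK cells and periportal hepatocytes, which did not pass as deposited, passed under at least 1 setting. Pseudocount alternatives were not run because the values are already log2. No paired analysis was possible because the animal numbers in the labels are not shared between groups. Without detection calls, signal over background is unknown, which limits dim genes such as Sgpl1 in knockout.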

Other observations

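Of the tests in this part, the lists of early and late granulocyte, further monocyte and further resident Kupffer cell genes were drawn up after the main results were seen and before their own members were looked at. The splits of the samples were counted after the gene counts were seen. The other genes here were named after their values were seen.

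Further monocyte genes, none of them in the lists above, rose in 8 of 10 tested cases and fell in none (limma). Ccr2, the receptor that guides monocytes out of the bone marrow, rose by 2.33 log2 (SE 0.27), Cybb, the oxidase of phagocytes, by 2.32, Plac8 by 2.29, Clec4e by 2.28 and Itgam by 1.57, while Cx3cr1 at 0.45 did not pass. Among late granulocyte genes, 4 of 6 rose, Fpr2 by 2.86 and Clec4d by 2.2. Outside any list, Lgals3 (galectin 3) rose by 4.32 log2 (SE 0.33), Cxcr4, a receptor that retains leukocytes in the marrow, by 3.31 (SE 0.19), and Ppbp, a platelet chemokine, by 3.73 (SE 0.27). Ubd, an inducible ubiquitin-like modifier, rose by 4.2 (SE 0.23), and A2m, a protease inhibitor, by 4.03 (SE 0.17).

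Outside the lists, the alcohol dehydrogenase gene Adh4 fell by 2.22 log2 (SE 0.25), the aldehyde oxidase gene Aox1 by 2.15 (SE 0.25), Prodh by 2.10 (SE 0.21), Sult2a8 by 2.48 (SE 0.25) and the corticosteroid carrier Serpina6 was at -2.06 (SE 0.45). In the glucose list, Foxo1 and Ppargc1a, regulators of glucose production, rose by 1.20 (SE 0.26) and 1.66 (SE 0.46).

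A hypothesis was that the granulocyte RNA came partly from immature cells. Early granulocyte genes rose in 3 of 3 tested cases, Ctsg by 2.15 log2, Ms4a3 by 0.774 and Fcnb by 0.677. Their median of 0.774 (95% bootstrap interval 0.677 to 2.15) stayed under the 1 log2 set beforehand, and 3 genes are too few to decide. In the neutrophil list, Prtn3, of the early-forming primary granules, rose by 4.53 log2 (SE 0.24), which goes with immature cells. Late granulocyte genes rose too, in 4 of 6 cases. Whether immature granulocytes were present is not settled by these values.

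Another hypothesis was a lower share of resident Kupffer cells. Further resident Kupffer cell genes fell in 2 of 9 cases, Folr2 (-1.94 log2) and Hpgd (-0.58), and Spic rose by 0.83. Their median of -0.149 (95% bootstrap interval -0.585 to 0.83) has members on both sides of 0, and other liver cells also express some of these genes, so fewer such cells and a changed state of them cannot be told apart here.

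The 6 animals can be split into 3 and 3 in 10 ways. The split by genotype gave 2482 changed genes and 4835 changed probe sets, and the highest other split gave 0 of each. For gene lists it gave 18, and the highest other split 14. In each case 1 of the 10 splits, the real one, gave a count as large, and 10 splits are too few for a share under 0.05. Every other split puts arrays of both genotypes in each arm. A difference between genotypes then widens the spread within arms and lowers the count by itself, so the contrast with 0 adds no separate evidence.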
